A study of Mus musculus with 8 samples.

How the data were processed

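RNA of epididymal white adipose tissue, the fat pad beside the epididymis, was measured in 8 samples of male C57BL/6 mice aged 12 to 15 weeks. The labels put 4 samples in a wild-type group and 4 in a group with a knockout of Rev-erb alpha, the nuclear receptor encoded by Nr1d1. Tissue was collected at Zeitgeber time 10, counted in hours from lights on in a day of 12 h light and 12 h dark, and mice ate standard chow, per the labels' protocols. Total RNA was extracted with TRIzol, cleaned on RNeasy columns, and labelled with biotin through whole-transcript kits of Ambion (WT Expression) and Affymetrix (GeneChip WT Terminal Labeling), per the labels' protocols. The labels number the replicates and do not say whether each came from a separate mouse, so the p-values measure the spread between these samples.

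The deposited values are log2 expression values, 1 per row of a whole-transcript Affymetrix mouse array and sample. The submitters' processing notes name the tool affy. The methods of background correction, normalization and summarization and the filters were not given in the sources used here. That the scale is log2 was read from the values, which ranged from 2.09 to 13.4 with array medians of 5.90 to 5.95. Processing that pulls array distributions together leaves changes relative to the bulk of the rows, so a shift shared by most genes would not be seen. No scanner intensities or detection calls were used here, so a dim row has no bound for its background.

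The platform annotation gave exactly 1 gene symbol to 20748 of the 23346 rows, several symbols to 1183 and none to 1415. Only rows with 1 symbol were tested, which covered 19310 genes, and 807 genes had more than 1 row. Of these rows, 20704 had an Entrez identifier in the mouse gene table, and none of those had a different symbol there. That table, of the GRCm38.p6 assembly, served only for names and for which genes neighbour each other. No genome build is given for the array rows, so no coordinates are printed.

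The contrast of knockout-labelled with wild-type arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, a 2-group design with no other term) on the deposited log2 values without a filter on dim rows. All limma p-values are two-sided, Benjamini-Hochberg adjustment ran over the tested rows, and a row was called changed at an adjusted p under 0.05. A log2 fold change is the knockout-labelled mean minus the wild-type mean, given with its standard error (SE) from the moderated fit, and group values are means ± SD with n = 4 arrays per group.

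Gene lists for 36 pathways and cell types were fixed from textbook knowledge, and each was tested with limma's camera at its preset inter-gene correlation of 0.01, on the brightest row of each gene. Benjamini-Hochberg adjustment ran over the 36 lists. Each list's mean shift was also compared between the groups of arrays with an exact two-sided permutation test, whose smallest p for 4 against 4 arrays is 0.0286. These permutation p-values were not adjusted over the lists. Members past the threshold were counted, on those same rows, after adjustment over all rows and, separately, adjusted over the list alone. Camera with a correlation estimated per list and fry (statmod 1.5.0) were alternatives. The groups, the tests, the lists and the rule for naming genes were set before the data were examined.

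Nr1d1, Klb and Arntl were always named. Also named were the 12 largest log2 fold changes in each direction among called rows whose 4 knockout-labelled arrays all lay on the same side of the 4 wild-type arrays, leaving out predicted genes and olfactory or vomeronasal receptors. From each list, up to 4 members with the smallest p were named, and every member that passed in lists with fewer than 10 members. Genes named outside this rule are said to be so in the text.

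The fit and camera were tested on simulated data with the real row means and spreads, over 20748 rows, for knockout against wild type. With 200 rows changed, 80% of the changes of 0.5 log2 and 99% of those of 1 log2 were recovered, and 4.79% of the 188 called rows were unchanged ones. No list was called without a simulated shift, and a list shifted by 0.4 log2 was recovered. Rows were simulated independently of each other, so the simulation does not test list calls where members vary together. In the real data the estimated correlation within the matrix list, for example, was 0.352.

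Alternatives were quantile normalization, median centring of each array, leaving out the dimmest 33.3% of rows, testing all rows, eBayes with trend and robust options, array weights, the replicate number as a block, leaving out each array in turn, a 1.5-fold minimum and an adjusted p under 0.10. For lists, the mean of all rows of a gene was also tried. Fits with only knockout-labelled arrays 1 and 2 or only 3 and 4 were added after the arrays were seen to part in this way. No pair of arrays held identical values. Rows with several symbols or none entered no comparison and are counted in the closing part.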

Results

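The arrays compared the transcriptome of epididymal white adipose tissue, a visceral fat depot, between 4 wild-type samples and 4 samples labelled as knockouts of Rev-erb alpha. Rev-erb alpha is a nuclear receptor that represses transcription and belongs to the circadian clock. Tissue was taken at Zeitgeber time 10, near the daily peak of the receptor's protein in wild-type mice according to the labels. The title of the series places the comparison in the context of signalling by the hormone FGF21 in fat. Array medians lay between 5.90 and 5.95 log2. Correlations over all rows, which are across genes and not between independent replicates, were 0.994 to 0.996 between wild-type arrays, 0.994 to 0.997 between knockout-labelled arrays and 0.989 to 0.994 across the groups. The number of arrays, 4 per group, limits the precision of every value.

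The row of the targeted gene, Nr1d1 (row 10390691), was not measurably lower in the knockout-labelled arrays. It read 9.47, 9.11, 9.18 and 9.83 log2 in the wild-type arrays (9.40 ± 0.33, n = 4) and 9.56, 9.28, 8.90 and 8.80 in the knockout-labelled arrays (9.14 ± 0.35, n = 4). The log2 fold change was −0.26 (SE 0.19, limma adjusted p = 0.479), and 0.03 with knockout-labelled arrays 1 and 2 alone. Which part of the transcript the row reads, and whether that part was deleted, was not given in the sources used here. A row outside the deleted part would check nothing. Since it is not known where this row lies, it cannot decide for or against the genotype labels, and the arrays are called knockout-labelled throughout.

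The knockout-labelled tissue differed from wild type in 1536 rows, 791 higher and 745 lower, which stood for 764 and 716 genes (limma, adjusted p under 0.05). Most of these changes were small. The median absolute log2 fold change among them was 0.37, and 53 rows were at least 2-fold higher and 27 at least 2-fold lower. In 3183 rows, 15.3% of those tested, the groups did not overlap, against 2.86% expected by chance. On the principal component with the largest variance, 43.2% of the total, the wild-type arrays lay between −15.0 and −12.2 and the knockout-labelled arrays between 9.34 and 19.02. A further component (14.7%) separated knockout-labelled arrays 1 and 2, at 12.8 and 10.7, from arrays 3 and 4, at −11.4 and −5.91. The number of changed rows was 972, 1004 and 913 without wild-type array 3, wild-type array 4 or knockout-labelled array 4. It was 701 with knockout-labelled arrays 1 and 2 only and 1822 with arrays 3 and 4 only, fits chosen after this separation was seen.

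The 12 largest increases among rows that the naming rule admits lay between 1.62 and 2.72 log2. The ribonuclease gene Rnase2a was higher by 2.72 log2 (SE 0.46, 6.60-fold), the small heat shock protein gene Hspb7 by 2.49 (SE 0.24, 5.61-fold) and the matrix glycoprotein gene Thbs2 by 2.29 (SE 0.40, 4.89-fold). The imprinted zinc finger genes Zim1 and Peg3 were higher by 2.05 (SE 0.35) and 1.85 (SE 0.20). Asb12, the endosomal gene Ehd3, the clock gene Arntl, the lysyl oxidase relative Loxl4, the monoacylglycerol acyltransferase gene Mogat2, the transcription cofactor gene Vgll3 and the palmitoyltransferase gene Zdhhc2 completed the 12, with log2 fold changes from 1.62 to 1.93. Limma adjusted p-values of the 12 ranged from 3.20e-05 for Arntl to 0.0271 for Mogat2. The second Loxl4 row was higher as well (1.22).

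By the same rule, the largest decreases were those of the cytochrome P450 gene Cyp2f2 and the small GTPase gene Rasd1. Cyp2f2 fell by 2.85 log2 (SE 0.25), from 9.38 ± 0.49 to 6.53 ± 0.41 (n = 4 each), and Rasd1 fell by 2.60 (SE 0.39). Another P450 gene, Cyp2e1 (−1.16, SE 0.22), the carboxylesterase gene Ces1f (−1.42, SE 0.22), the sulfurtransferase gene Tst (−1.42, SE 0.15) and the acetyl-CoA carboxylase gene Acacb (−1.26, SE 0.25) fell. Serpina3b (−1.66), the interferon-inducible gene Ifi27l2a (−1.64), the angiopoietin gene Angpt1 (−1.58), Nabp1 (−1.34), the collagen VI gene Col6a5 (−1.22) and Zyg11a (−1.14) were the others of the 12, and the second Col6a5 row was also lower (−0.64). Limma adjusted p-values ran from 0.000177 for Cyp2f2 to 0.0163 for Nabp1.

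The size of several large changes differed between the knockout-labelled arrays. Thbs2 read 9.77 and 10.15 log2 in arrays 1 and 2 and 7.93 and 8.54 in arrays 3 and 4, against 6.59 to 6.91 in wild type. Rnase2a read 7.12 and 7.11 in arrays 1 and 2 and 9.55 and 7.58 in arrays 3 and 4, and Mogat2 read 6.78 and 6.36 against 8.57 and 7.82. Of the genes named in these 2 sets of 12, calls were lost when an array was left out for Mogat2 (each wild-type array or knockout-labelled array 4, adjusted p 0.0563 to 0.0818) and Nabp1 (wild-type array 3 or 4 or knockout-labelled array 4, 0.0504 to 0.0524), and for both with trend and robust eBayes (0.0796 and 0.0538).

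**Figure D1:**
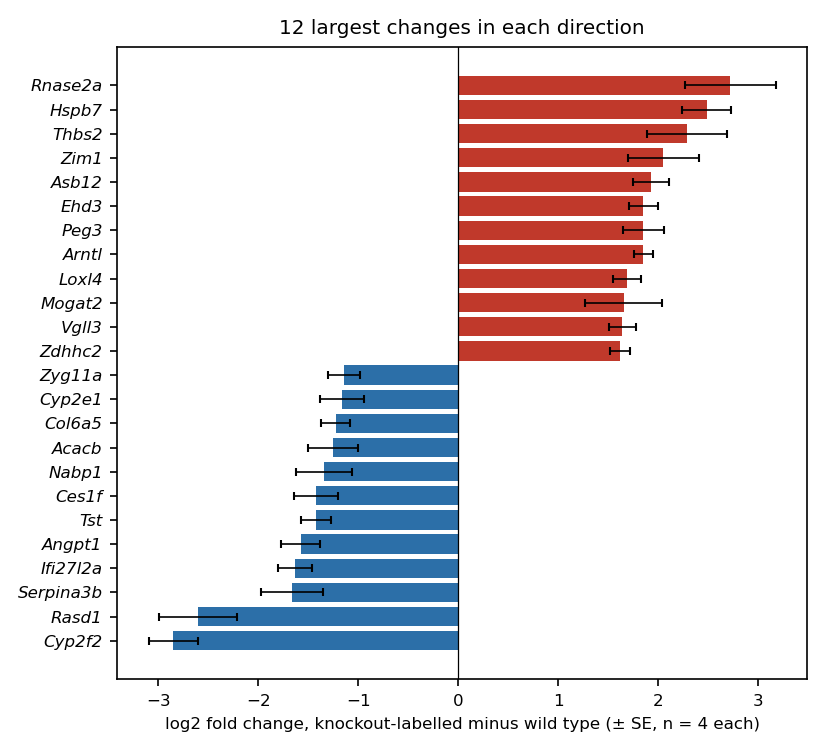
Log2 fold changes, knockout-labelled minus wild type (horizontal axis), of the 12 genes with the largest increases (red) and the 12 with the largest decreases (blue); bars start at 0 and whiskers are ± 1 SE from the moderated fit, n = 4 arrays per group. Values run from −2.85 for Cyp2f2 to 2.72 for Rnase2a.

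Of 6 measured clock genes with binding elements for Rev-erb and ROR receptors, counted like every list by the brightest row of each gene, Arntl, Nfil3 and Clock rose in the knockout-labelled tissue. Arntl (row 10556463), which encodes the clock activator BMAL1, went from 5.02 ± 0.17 to 6.87 ± 0.15 log2 (n = 4 each), a 3.61-fold difference (log2 fold change 1.85, SE 0.098, limma adjusted p = 3.20e-05). Nfil3, a repressor of D-box genes, was 2.79-fold higher (log2 fold change 1.48, SE 0.17) and Clock, the partner of BMAL1, 1.63-fold higher (0.71, SE 0.078). These 3 of the 6 measured members of the list passed, over all rows and adjusted over the list alone, and the median log2 fold change was 0.44, or 0.71 with the dimmest 33.3% of rows left out. The log2 fold changes of Ninj1 (0.17, adjusted p = 0.187) and, chosen after their values were seen, of E2f8 (−0.14, 0.321) and Cry1 (−0.03, 0.858) did not pass, and that of Cry1 changed sign when an array was left out (−0.0731 to 0.0158). The list passed camera (adjusted p = 0.00119; adjusted p = 0.260 with an estimated correlation), and its mean shift differed between the groups (exact permutation p = 0.0286, the smallest possible).

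Clock genes driven through E-box or D-box elements included changes in both directions. Hlf (0.51, SE 0.079) and Cry2 (0.48, SE 0.090), which encode a D-box activator and a clock repressor, were higher, while the period gene Per3 (−0.49, SE 0.11) and the deubiquitinase gene Usp2 (−0.46, SE 0.11) were lower. The other 10 of the 14 measured members did not pass, and the list did not pass as a whole (median −0.08, or −0.138 to −0.00527 with single arrays left out, camera adjusted p = 0.530). With knockout-labelled arrays 3 and 4 alone it was called (median −0.20, adjusted p = 0.0258), and with arrays 1 and 2 alone its median was 0.0283 (adjusted p = 0.667). Adjusted over the list alone, 2 were higher and 3 lower. The call of Per3 was lost without wild-type array 3 or 4 or knockout-labelled array 4 (adjusted p 0.0613 to 0.0682), and that of Usp2 without wild-type array 1, 2 or 3 or knockout-labelled array 3 or 4 (0.0631 to 0.0942).

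Of the genes for FGF21 and its receptors, the co-receptor gene Klb rose. Klb (row 10522127), which encodes beta-klotho, went from 7.72 ± 0.20 to 8.95 ± 0.27 log2 (n = 4 each), a 2.36-fold difference (log2 fold change 1.24, SE 0.13, limma adjusted p = 0.000540), and every knockout-labelled array lay above every wild-type array. The receptor gene Fgfr2 was lower (−0.30, SE 0.078, adjusted p = 0.0426). The log2 fold change of Fgfr1, a receptor gene, was 0.19 (SE 0.058, adjusted p = 0.0736), and that of Fgf21 itself was −0.09 (SE 0.066, adjusted p = 0.509) at 4.69 ± 0.10 in wild type. The other 5 of the 7 measured members did not pass, and the list as a whole did not pass (camera adjusted p = 0.833). Adjusted over the list alone, 2 members were higher and 1 lower. The Fgfr2 call was lost when any array but wild-type array 4 was left out (adjusted p 0.0511 to 0.117) and with quantile normalization (0.0524), and Fgfr1 passed without knockout-labelled array 3 (0.0350).

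Feedback and early genes of FGF and ERK signalling showed 3 increases among 15 measured members and no decrease that passed. The feedback inhibitor genes Spry4 and Spry1 were higher by 0.49 (SE 0.095, limma adjusted p = 0.0117) and 0.41 (SE 0.096, 0.0273), and the early gene Fos by 0.21 (SE 0.055, 0.0454). The list did not pass (camera adjusted p = 0.725), and the same number passed adjusted over the list alone. The Spry1 call was lost with any wild-type array or knockout-labelled array 3 or 4 left out (adjusted p 0.0525 to 0.0789), and the Fos call in every fit with an array left out (0.0627 to 0.102) and with trend and robust eBayes (0.0602).

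**Figure D2:**
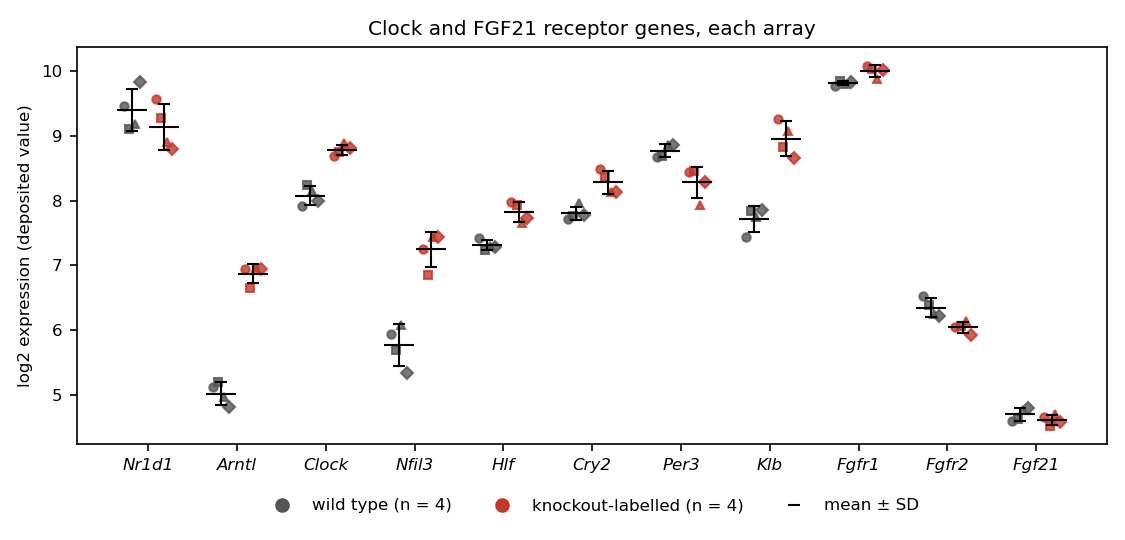
Deposited log2 expression (vertical axis) of 11 clock and FGF21 receptor genes in 4 wild-type (grey) and 4 knockout-labelled (red) arrays; the marker shapes circle, square, triangle and diamond are replicates 1 to 4, and black bars are mean ± SD. The groups overlap for Nr1d1 and separate for Arntl (5.02 and 6.87) and Klb (7.72 and 8.95).

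The extracellular matrix list shifted up in camera at the preset correlation and in fry (fry adjusted p = 0.00679). It did not pass camera with an estimated correlation (adjusted p = 0.326). Of 21 measured members, 14 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median log2 fold change of 0.45. Lox, which crosslinks collagen, was 2.47-fold higher (1.31, SE 0.091), the collagen VI genes Col6a1 and Col6a2 were 2.48-fold and 2.33-fold higher (1.31, SE 0.11, and 1.22, SE 0.14), and the basement membrane collagen gene Col4a2 was 1.59-fold higher (0.67, SE 0.078). The log2 fold change of Col6a3, chosen after its value was seen, was 0.15 (limma adjusted p = 0.603), 0.0095 to 0.285 with single arrays left out and −0.09 with knockout-labelled arrays 1 and 2 alone. It was 1 of 7 members that did not pass, of which Timp2, also chosen after its value was seen, was below 0 (−0.16, 0.286). The list passed camera (adjusted p = 4.59e-14; adjusted p = 0.326 with an estimated correlation), and its mean shift differed between the groups (exact permutation p = 0.0286). With knockout-labelled arrays 1 and 2 alone the median was 0.25 and with arrays 3 and 4 alone 0.54.

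The list of adipose progenitor and fibroblast markers also passed camera upwards at the preset correlation, with a smaller median. It did not pass with an estimated correlation (adjusted p = 0.594) or with fry (adjusted p = 0.0693). Of 17 measured members, 6 were higher and 0 lower, with the same counts adjusted over the list alone, and the median log2 fold change was 0.14. Col1a1 (0.71, SE 0.086), which the matrix list holds too, Mfap5 (0.84, SE 0.12), Anxa3 (0.51, SE 0.082) and Cd55 (0.56, SE 0.13) had the smallest p. Among widely used markers of these cells, chosen after their values were seen, Pdgfra was at 0.14 (limma adjusted p = 0.552; 0.0247 to 0.224 with single arrays left out) and Dcn at −0.14 (0.233). The list passed camera (adjusted p = 0.000726; adjusted p = 0.594 with an estimated correlation; exact permutation p = 0.0286 for its mean shift). The median was 0.22 without wild-type array 1 and 0.09 without wild-type array 3, and the Cd55 call was lost without wild-type array 2 or 3 or knockout-labelled array 3 or 4 (adjusted p 0.0572 to 0.0881).

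Endothelial markers had 3 increases among 16 measured members, with the same count adjusted over the list alone. The tight junction gene Cldn5 was 1.98-fold higher (0.99, SE 0.12), and the lymphatic marker Lyve1 (0.53, SE 0.13) and the vascular marker Pecam1 (0.20, SE 0.052) were higher too. The median log2 fold change was 0.11, the list passed camera (adjusted p = 0.0235; adjusted p = 0.326 with an estimated correlation) and its mean shift differed between the groups (exact permutation p = 0.0286). The list was not called without wild-type array 1 or 2 (adjusted p 0.0526 and 0.0539), nor with knockout-labelled arrays 1 and 2 alone (0.0509, median 0.0552), and its median was 0.07 without knockout-labelled array 3. The Lyve1 call held only without wild-type array 2 and the Pecam1 call only without knockout-labelled array 2, with limma adjusted p of 0.0537 to 0.0937 and 0.0724 to 0.112 in the other cases, and Pecam1 was also lost with quantile normalization (0.0712).

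Lists of markers of other cell types did not pass camera. Among smooth muscle and pericyte markers Acta2 (0.89, SE 0.16) and Rgs5 (0.66, SE 0.12) were higher and Tagln (−0.29, SE 0.074) lower, of 12 measured (camera adjusted p = 0.824). Among 16 mature adipocyte markers the leptin gene Lep (0.75, SE 0.13) and the glycerol channel gene Aqp7 (0.39, SE 0.067) were higher and the adipogenic factor gene Cebpa (−0.37, SE 0.058) lower (camera adjusted p = 0.802; 3 higher and 4 lower adjusted over the list alone). The mesothelial markers Msln (0.60, SE 0.069) and Efemp1 (0.29, SE 0.065) were higher of 12 (0.824; 2 higher and 1 lower adjusted over the list alone), the macrophage marker Cd14 (−0.38, SE 0.073) was lower of 19 (0.807), the muscle marker Actn3 (−0.43, SE 0.10) was lower of 13 (0.802) and the neural marker Uchl1 (0.52, SE 0.077) was higher of 10 (0.725; 1 higher and 1 lower adjusted over the list alone). Calls were lost for Tagln (each wild-type array left out, or knockout-labelled array 3 or 4, limma adjusted p 0.0681 to 0.102), Efemp1 (wild-type array 3 or 4 or knockout-labelled array 2, 3 or 4, 0.0523 to 0.0732) and Actn3 (wild-type array 2, 3 or 4 or knockout-labelled array 1, 3 or 4, 0.0740 to 0.0970). Tagln and Actn3 were also lost with quantile normalization (0.0510 and 0.0502) and Tagln with median centring (0.0570).

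The list of fatty acid oxidation genes shifted down in camera at the preset correlation. It did not pass camera with an estimated correlation (adjusted p = 0.622) or fry (adjusted p = 0.0518). Of 20 measured members, 7 were lower and 0 higher (9 and 0 adjusted over the list alone), with a median log2 fold change of −0.12. The peroxisomal enzyme gene Ehhadh (−0.84, SE 0.084), the receptor gene Ppara (−0.39, SE 0.064), the carnitine transfer gene Cpt1a (−0.34, SE 0.057) and the dehydrogenase gene Acadl (−0.39, SE 0.090) were lower. The list passed camera (adjusted p = 0.00369, and 0.622 with an estimated correlation). It was not called with knockout-labelled arrays 1 and 2 alone (camera adjusted p = 0.06005). Its mean shift differed between the groups (exact permutation p = 0.0286), but by a narrow margin. The lowest wild-type array, array 1, lay at 0.0148 and the highest knockout-labelled array, array 1, at 0.0038. The Acadl call was lost without wild-type array 1, 3 or 4 or knockout-labelled array 4 (limma adjusted p 0.0640 to 0.0804).

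The respiratory chain and ribosomal protein lists passed camera downwards at the preset correlation, with few or no members that passed. Counting the brightest row of each of 25 respiratory chain genes, only Ndufa4 was lower (−0.26, SE 0.060), over all rows and adjusted over the list alone, and the median was −0.08 (camera adjusted p = 0.0292; adjusted p = 0.781 with an estimated correlation; exact permutation p = 0.0857). Of the brightest rows of 19 ribosomal protein genes 0 passed limma's test over all rows or adjusted over the list alone, 6 were lower at an unadjusted p under 0.05, and the median was −0.08 (camera adjusted p = 0.0307; adjusted p = 0.770 with an estimated correlation; exact permutation p = 0.0571). Dimmer rows of Cox5b (−0.24, limma adjusted p = 0.0335) and Rps14 (−0.34, 0.00988), members of these lists chosen after their values were seen, were lower, while their brightest rows did not pass (0.258 and 0.0506). The brightest Rps14 row passed with quantile normalization (0.0489), the dimmest 33.3% of rows left out (0.0341), trend and robust eBayes (0.0348), without knockout-labelled array 2 (0.0401) and with knockout-labelled arrays 3 and 4 alone (0.0259). Both list calls were lost with the dimmest 33.3% of rows left out (adjusted p = 0.0940 for each). They were also lost without wild-type array 3 or knockout-labelled array 2 or 4 for the respiratory chain (0.0767 to 0.0932) and without wild-type array 1 or 2 or knockout-labelled array 1 or 4 for the ribosomal genes (0.0526 to 0.168), whose median was −0.12 without wild-type array 3. With knockout-labelled arrays 1 and 2 alone neither list was called (0.169 and 0.0509), and with arrays 3 and 4 alone the ribosomal list was not (0.0625), nor was it with the mean of all rows of a gene (0.0726). The Ndufa4 call was lost without wild-type array 2, 3 or 4 or knockout-labelled array 2, 3 or 4 (0.0519 to 0.0754).

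Genes of insulin signalling and glucose use included 5 decreases and no increase that passed, among 18 measured members. The insulin receptor substrate genes Irs1 (−0.84, SE 0.15) and Irs2 (−0.58, SE 0.12), the hexokinase gene Hk2 (−0.50, SE 0.081), the glycogen synthase gene Gys1 (−0.39, SE 0.068) and the kinase subunit gene Pik3r1 (−0.45, SE 0.10), which the naming rule did not take, were lower. Adjusted over the list alone, 7 were lower and 4 higher. The list had camera adjusted p = 0.0607, and it was called without wild-type array 1 (0.0413), without knockout-labelled array 1 (0.0285), with quantile normalization (0.0405), with median centring (0.0368) and with knockout-labelled arrays 3 and 4 alone (0.0318). It also passed fry's directional test (adjusted p = 0.0216), but not camera with an estimated correlation (adjusted p = 0.369). Calls were lost for Irs2 without wild-type array 2 or 4 or knockout-labelled array 4 (limma adjusted p 0.0521 to 0.0555) and for Pik3r1 without wild-type array 2, 3 or 4 or knockout-labelled array 1, 3 or 4 (0.0524 to 0.0749).

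Of 22 measured lipid synthesis genes 4 were lower, and no increase passed. These were Acacb, the glycerol acyltransferase gene Gpam (−0.51, SE 0.071), the transcription factor gene Srebf1 (−0.67, SE 0.11) and Dgat1 (−0.30, SE 0.072), and adjusted over the list alone 5 were lower and 2 higher. The list had camera adjusted p = 0.119 and was called without knockout-labelled array 1 (0.0285) and with the replicate number as a block. Of 15 lipolysis and droplet genes Aqp7 and the monoglyceride lipase gene Mgll (0.27, SE 0.054) were higher and G0s2 (−0.72, SE 0.15), which encodes a lipase inhibitor, was lower (camera adjusted p = 0.824; 3 higher and 4 lower adjusted over the list alone). Of 11 lipid uptake genes the transporter gene Slc27a1 (−0.84, SE 0.17) was lower and the lipoprotein receptor gene Vldlr (0.40, SE 0.097) higher (0.802; 3 higher and 1 lower adjusted over the list alone), and of 15 cholesterol synthesis genes Hmgcs1 (0.91, SE 0.16) was higher (0.686). Calls were lost for Dgat1 (each wild-type array left out, or knockout-labelled array 2 or 4, limma adjusted p 0.0548 to 0.0922), Slc27a1 (wild-type or knockout-labelled array 4, 0.0522 and 0.0566) and Vldlr (each array but knockout-labelled array 2, 0.0587 to 0.0955).

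Brown and beige fat genes moved both ways, with 2 higher and 3 lower of 17 measured (camera adjusted p = 0.682; 2 and 4 adjusted over the list alone). The transcription factor gene Ebf2 (−0.79, SE 0.071) and the coactivator genes Ppargc1b (−0.52, SE 0.085) and Ppargc1a (−0.56, SE 0.10) were lower, and the potassium channel gene Kcnk3 (0.84, SE 0.12) and Cox7a1 (0.33, SE 0.071), which the naming rule did not take, were higher. Of the heme and redox list Alad (−0.51, SE 0.065) and Txnrd1 (−0.24, SE 0.065) were lower of 17 (0.126; 3 lower adjusted over the list alone), and its mean shift differed between the groups (exact permutation p = 0.0286). The heme and redox list also passed fry's directional test (adjusted p = 0.0143), but not camera with an estimated correlation (adjusted p = 0.520). Of the unfolded protein response list Xbp1 (−0.45, SE 0.054) and Asns (−0.38, SE 0.059) were lower of 20 (camera adjusted p = 0.914). The inflammation list had 1 increase of 21, Ptgs2 (0.42, SE 0.068; 0.682), and the early and heat shock list had Fos and Hspb1 (0.32, SE 0.077) higher of 17 (0.530). Calls were lost for Txnrd1 (left out: each array but knockout-labelled array 4, limma adjusted p 0.0574 to 0.125), Hspb1 (wild-type array 1, 2 or 4 or knockout-labelled array 2, 3 or 4, 0.0671 to 0.0895) and Cox7a1 (wild-type array 2 or 3 or knockout-labelled array 3 or 4, 0.0516 to 0.0577). The second rows of Ppargc1a (−0.70) and Hspb1 (0.44, adjusted p = 0.00813) changed in the same direction. Txnrd1 was also lost with quantile normalization (0.0576), median centring (0.0688) and all rows tested (0.0541).

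Of 28 listed neighbours of Nr1d1 on chromosome 11, 3 were lower and 0 higher (camera adjusted p = 0.0912; 4 and 0 adjusted over the list alone). Of the 28, 21 lay below 0, the mean shift differed between the groups (exact permutation p = 0.0286) and the list passed fry (adjusted p = 0.0284). The thyroid hormone receptor gene Thra (−0.33, SE 0.052, limma adjusted p = 0.00413) and Msl1 (−0.27, SE 0.053, adjusted p = 0.0117) were lower, and these were the genes next to Nr1d1 on either side among those measured. Smarce1 was lower in its brightest row (−0.43, SE 0.095, 0.0218), while its other rows, at −0.18 and −0.17, did not pass (0.106 and 0.0776). Which of these rows reads the gene at this locus was not given in the sources used here, so the count of 3 includes 1 gene that is uncertain. The Smarce1 call was lost without wild-type array 2, 3 or 4 or knockout-labelled array 2 or 3 (0.0532 to 0.0647).

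The lists for T and NK cells, B cells, granulocytes and mast cells, red cells, male germ cells, epididymal epithelium, interferon response, cell cycle and the nuclear receptor corepressor complex had no member whose brightest row passed limma's test, and camera adjusted p was 0.188 or higher. The mean shift of the epididymal list nevertheless differed between the groups, with all knockout-labelled arrays below all wild-type arrays (exact permutation p = 0.0286, median −0.08). In all, the mean shift separated the groups, in either direction, for 8 of the 36 lists, against 2.86% expected by chance for arrays without a group difference. The groups also did not overlap in 15.3% of single rows, and some lists share members. The count of 8 therefore does not show that these lists differ more than other sets of genes would. The T and NK cell list was called with knockout-labelled arrays 3 and 4 alone (median −0.13, adjusted p = 0.0320). With the ribosomal list, these 10 lists held 141 measured members, of which 18 had an unadjusted p under 0.05. In all, 7 of the 36 lists passed camera, 4 up and 3 down. With an estimated correlation 0 passed, and 4 had an unadjusted p under 0.05. Fry's directional test passed 6 lists, 3 of them among the 7 (clock genes with Rev-erb elements, matrix and endothelial). The others were the insulin and glucose, heme and redox, and Nr1d1 neighbour lists. Of the 35 splits of the 8 arrays into groups of 4, 10 called at least 7 lists, the genotype split included. The median, mean and test direction differed in sign for 8 lists, none of them called, namely those of cholesterol synthesis, FGF and ERK response, lipid uptake, skeletal muscle, adipocytes, smooth muscle, FGF21 receptors and unfolded protein response.

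**Figure D3:**
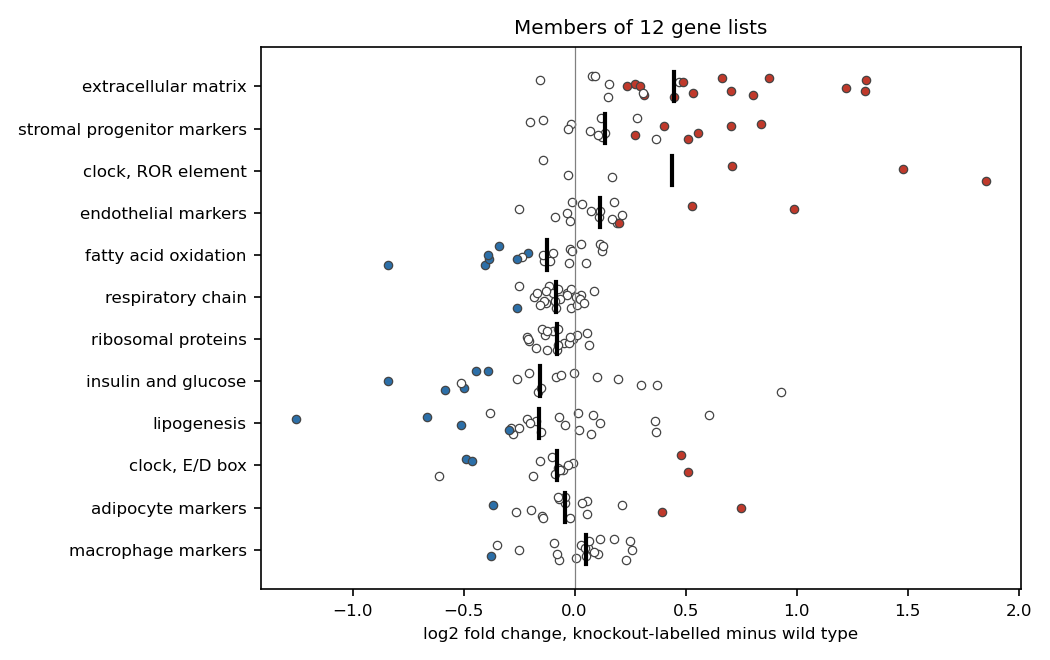
Log2 fold change, knockout-labelled minus wild type (horizontal axis), of each measured member of 12 gene lists; filled points passed limma's adjusted p under 0.05 (red higher, blue lower), open points did not, and black ticks are list medians. The matrix list has 14 filled points and a median of 0.45, and fatty acid oxidation has 7 and a median of −0.12.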

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

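The tests of the Nr1d1 row, of the stromal share, of the matrix shift in single arrays and of the Nr1d1 neighbours were chosen after the results were seen, and the test of the pairs of knockout-labelled arrays was written down before its result.

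In 13 of 308 groups of 4 arrays, over 118 genes and 36 lists, a single array stood apart from the other 3 by more than Dixon's 95% critical value, and chance does this in about 1 of 20 groups. Knockout-labelled array 2 stood apart for Arntl (6.65 log2, the others 6.94 to 6.95), Zdhhc2 (7.496, the others 7.60 to 7.62) and Actn3 (6.08, the others 5.70 to 5.74). Knockout-labelled array 3 stood apart for Cryab (10.95, the others 10.82 to 10.84). Wild-type array 1 stood apart for Rasd1 (7.98, the others 9.58 to 9.76), Pik3r1 (10.88, the others 11.31 to 11.32) and the mean shift of the adipocyte list (−0.0854, the others 0.0162 to 0.0323). Wild-type array 2 stood apart for Acadl (9.28, the others 9.41 to 9.42), wild-type array 3 for Thbs2 (6.59, the others 6.85 to 6.91), Anxa3 (7.99, the others 8.29 to 8.32) and Cox5b (10.98, the others 10.76 to 10.79). Wild-type array 4 stood apart for Arhgef37 (4.57, the others 4.397 to 4.42) and for the mean shift of the clock list with Rev-erb elements (−0.47, the others −0.31 to −0.28).

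Rows with several symbols or none entered no comparison. When all rows were tested, 127 of these 2598 rows changed, 56 higher and 71 lower.

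The Nr1d1 row was not measurably lower in the knockout-labelled arrays. A mix-up of labels would leave an array out of place on other genes, but the lowest knockout-labelled array lay 1.45 log2 above the highest wild-type array for Arntl, against a within-group SD of at most 0.17. The row stayed bright, at a mean percentile of 93.6 of all rows in the knockout-labelled arrays, as it would if it read a retained part of the transcript. A row that reads another transcript would be bright too, so these cannot be told apart without the probe positions. A hypothesis that remains open is that the altered allele may still make RNA that this row reads.

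The matrix list was higher in the knockout-labelled tissue at the preset correlation (camera adjusted p = 4.59e-14) but not with an estimated one (0.326), and 7 of its 21 members did not pass. If a larger share of stromal cells raised all their markers alike, the matrix list and other stromal markers would shift by as much. The matrix list shifted by 0.50 and 15 progenitor markers outside it by 0.21, a difference of 0.29 (exact permutation p = 0.0286, the smallest possible). This argues against a uniform rise in share as the only source. The markers moved unequally (Mfap5 0.84, Dcn −0.14), and a rise in a part of these cells was not tested, so a change in cell share is not excluded. A part of the matrix rise may still come from a larger stromal share, since 4 of these 15 markers were higher and 0 lower. The list passed with 2 of the 2 pairs of knockout-labelled arrays, which shows little by itself, since both fits share the wild-type arrays and camera at the preset correlation called lists in other splits too. The medians were 0.25 with arrays 1 and 2 and 0.54 with arrays 3 and 4, so the size was not the same in both pairs. The lowest knockout-labelled array lay 0.307 log2 above the highest wild-type array in the list's mean shift, against an SD of 0.048 among the wild-type arrays, so the shift was not confined to 1 pair. Other matrix-producing cells and an altered state of the stromal cells were not tested, and any effect of the knockout remains a hypothesis.

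The genes on either side of Nr1d1, Thra and Msl1, were lower. A segment of another strain left around a targeted locus could change neighbouring genes, and then more of the nearby genes should have changed than elsewhere. Of the 40 nearest measured genes 7.5% changed (3 genes, exact 95% interval 1.57% to 20.4%), against 7.499% of all other genes (Fisher's exact p = 1, two-sided). Smarce1, 1 of the 3, rests on a row that may read elsewhere, since its other rows did not pass. The 28 listed neighbours did differ between the groups in their mean shift (exact permutation p = 0.0286), with 21 below 0. The interval is wide enough to hold a moderate excess, and the mouse line's history was not given in the sources used here, so a strain segment, a local effect of the altered allele and a response to loss of the receptor cannot be told apart.

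Of the 35 splits of the 8 arrays into groups of 4, 1 gave as many changed rows as the genotype split (1536), and that was the genotype split itself. The highest count among the others was 0, with 353 to 1711 rows at an unadjusted p under 0.05 against 4542. The genotype split thus gave the highest count, but 1 of 35 is the smallest share that this comparison can give. Every other split mixes wild-type and knockout-labelled arrays, so a difference between the genotype groups adds to its spread and lowers its count. The comparison therefore cannot exclude chance for the number of rows, and it cannot show what made the groups differ. For gene lists, 10 of the 35 splits called at least the 7 of the genotype split, and the highest other count was 9, so chance cannot be excluded for the number of lists called at the preset correlation.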

How the results depend on the processing

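The fits with 2 of the knockout-labelled arrays were chosen after the data were seen. All counts are of rows past an adjusted p under 0.05 unless said otherwise. Against 1536 changed rows (791 higher, 745 lower), 1507 to 1879 changed with another scaling, row filter, variance model or array weights, and no row called in the reported fit turned direction in any of the fits. Median centring gave 914 higher and 593 lower, so that 60.7% of the changed rows were higher, against 51.5%. The 1.5-fold minimum left 326 (210 and 116) and an adjusted p under 0.10 gave 2552 (1236 and 1316), by construction. Leaving out single arrays gave 913 to 1418 rows, 499 to 747 higher and 414 to 671 lower, with 1 array fewer. The knockout-labelled arrays 1 and 2 alone gave 701 (403 and 298), of which 581 were among the 1536, and arrays 3 and 4 alone 1822 (1109 shared). The cause of this difference was not tested. No pairing of the samples by replicate number was seen, which cannot show that there is none. Correlations of same-number deviations were −0.07 to 0.13, and 2 of 8 arrays correlated best with their own number. With the replicate number as a block 1105 rows changed and 8 lists were called. Of 106 named genes with a call, 63 kept it in every fit that tested them, and calls were lost by 5 with quantile normalization, 2 with median centring, 3 with trend and robust options, 1 with all rows, 13 with the block, 40 with knockout-labelled arrays 1 and 2 alone and 13 with arrays 3 and 4 alone. Klb stayed between 1.14 and 1.34 and Arntl between 1.78 and 1.93 when single arrays were left out, while Nr1d1 stayed between −0.40 and −0.12 and was 0.0265 with knockout-labelled arrays 1 and 2 alone. Cry1 lay between −0.0731 and 0.0158 when single arrays were left out.

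The number of lists called was 5 to 8 with single arrays left out, 3 with knockout-labelled arrays 1 and 2 alone (clock genes with Rev-erb elements, matrix and progenitors), 9 with arrays 3 and 4 alone, and 0 with an estimated correlation. The estimated correlation was 0.352 for the matrix list, 0.356 for progenitors and 0.274 for fatty acid oxidation. It was 0.224 for the respiratory chain and 0.230 for ribosomal genes. Values above the preset 0.01 make camera stricter, which may account for a part of the loss of these lists. For endothelial markers (0.0120) and clock genes with Rev-erb elements (−0.00179) it was close to the preset or below it. A higher correlation does not explain the loss of those lists. Their unadjusted camera p rose from 9.95e-05 to 0.00721 (clock genes with Rev-erb elements) and from 0.00326 to 0.0272 (endothelial). Camera with an estimated correlation was thus stricter even where the correlation hardly changed. A list lost under it need not have members that vary together, and what made it stricter there was not tested. With arrays 3 and 4 alone the E-box and D-box clock (adjusted p = 0.0258), insulin (0.0318) and T cell (0.0320) lists were called as well, and the ribosomal list was not (0.0625). Lists that were not called in the reported fit could turn in the direction of their test, for causes not tested, and the values given are their medians. With knockout-labelled arrays 1 and 2 alone the medians were 0.0283 for E-box and D-box clock genes, −0.108 for cholesterol synthesis, 0.0413 for interferon, 0.0281 for adipocytes, 0.0134 for T cells, −0.0173 for smooth muscle, −0.0215 for mesothelium and −0.0339 for skeletal muscle, and the genes Col6a3 and Cry1 were at −0.0881 and 0.0844. With arrays 3 and 4 alone they were −0.0875 for lipolysis, −0.0547 for inflammation, 0.0681 for the unfolded protein response, 0.0503 for cell cycle, −0.00289 for macrophages and −0.0442 for B cells. Without the dimmest 33.3% of rows they were 0.0256 for the unfolded protein response and −0.00983 for cell cycle, and the unfolded protein response was at 0.0256 with the block. Fry turned the mesothelial list (−0.138). With single arrays left out, medians of the lists that turned in at least 1 fit were −0.118 to −0.0508 for FGF21 receptors, −0.0357 to 0.0566 for inflammation, −0.106 to 0.0316 for interferon, 0.00783 to 0.0484 for the unfolded protein response, −0.0755 to −0.00697 for cell cycle, −0.0121 to 0.118 for macrophages, −0.151 to −0.0288 for T cells, −0.0238 to 0.0544 for B cells, −0.0486 to 0.0152 for smooth muscle, −0.186 to −0.0588 for mesothelium, −0.00785 to 0.0381 for germ cells and −0.139 to 0.0503 for red cells.

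No background signal or detection call was used, so a change in a dim row may be understated by an unknown amount, and leaving out the dimmest 33.3% of rows moved the count of changed rows to 1879.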

Other observations

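The genes and families in this part were chosen after their values were seen, as was the test of imprinted genes.

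Among the rows with the smallest p, several genes outside the lists changed by about 2-fold with little spread between arrays. Cryab, which encodes the small heat shock protein alpha B-crystallin, was 2.16-fold higher (log2 fold change 1.11, SE 0.061, limma adjusted p = 3.20e-05). The elastic fibre gene Fbln5 (0.96, SE 0.067), the milk fat globule gene Mfge8 (0.90, SE 0.058) and Arhgef37 (1.00, SE 0.064) were higher as well. The desaturase gene Fads1 (−1.01, SE 0.058) and Nrg4 (−1.01, SE 0.064), which encodes a neuregulin secreted by fat, were lower. The amino acid transporter gene Slc7a8 was 2.96-fold higher (1.57, SE 0.15).

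For 7 gene families, picked because members had changed, the changed members were counted, which tests no shift of a family. Of 44 measured collagen genes 12 were higher and 1, Col6a5, was lower. Of 10 small heat shock genes 4 were higher, namely Cryab, Hspb7, Hspb6 (0.45, SE 0.071) and Hspb1, and 0 were lower. Thbs2, Thbs1 (1.35, SE 0.23) and Thbs4 (0.30, SE 0.070) were higher among 4 thrombospondin genes, and Lox and Loxl4 among 4 lysyl oxidase genes. Of 82 cytochrome P450 genes Cyp2u1 (0.40, SE 0.088) was higher and Cyp2f2, Cyp2e1 and Cyp1a1 (−0.28, SE 0.067) lower, of 15 Slc7 transporter genes Slc7a8 and Slc7a6 (0.72, SE 0.064) were higher, and of 15 desaturase and elongase genes Fads1 was lower. No changed row turned its direction under any alternative, quantile normalization and median centring included. Calls were lost for Cyp1a1 without wild-type array 1, 2 or 3 or knockout-labelled array 1 or 3 (limma adjusted p 0.0663 to 0.0814) and for Cyp2u1 without wild-type array 2, 3 or 4 or knockout-labelled array 1 or 4 (0.0503 to 0.0631). The Thbs4 call was lost without wild-type array 1, 2 or 3 or knockout-labelled array 2 or 3 (limma adjusted p 0.0590 to 0.0704) and the Hspb1 call without wild-type array 1, 2 or 4 or knockout-labelled array 2, 3 or 4 (0.0671 to 0.0895), while a second Hspb1 row was higher by 0.44 (adjusted p = 0.00813).

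Peg3 and Zim1, imprinted genes, were among the largest increases, which led to the hypothesis that imprinted genes change more often than other genes of like expression. Without Peg3 and Zim1, 10 of the 41 measured genes on the list of imprinted genes used here changed, 7 higher and 3 lower. In 10000 random lists of the same size matched on mean expression the median was 3 and the 95th percentile 6 (permutation of list membership, p = 7.0e-04), which is consistent with the hypothesis. Random lists treat genes as independent, and imprinted genes that vary together could pass more easily. The list need not hold every imprinted gene, and random lists do not allow for how its genes were chosen. They were matched on mean expression only. Peg10 (1.09, SE 0.13), Plagl1 (0.58, SE 0.091) and Cdkn1c (0.36, SE 0.055) were higher, and Impact (−0.40, SE 0.048) was lower.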
